A study of Triticum aestivum with 15 samples.

How the data were processed

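The samples were 12 leaf and 3 root libraries of hydroponically grown bread wheat, in 5 groups of 3. Groups, days and replicate numbers were taken from the sample titles, and plant numbers from the column names that the sample descriptions give. Per the labels' protocols, about 50 mg of frozen tissue was homogenised per sample, libraries came from a stranded mRNA kit, and paired-end reads of 150 nt were sequenced on an Illumina NovaSeq X Plus.

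The authors deposited 1 table of raw counts per gene for all 15 libraries, and its values are whole-number counts without normalization. Per the submitters' processing notes, the tools were FastQC 0.74, MultiQC 1.11, Trim Galore 0.6.7, HISAT2 2.2.1, StringTie 2.2.3 and featureCounts 2.0.3. The genome build, the annotation version, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of near-identical copies, among them the A, B and D copies of a gene, neighbouring duplicates and overlapping or antisense genes, are therefore uncertain for single genes, those named included. Reads of Fielder that differ from the reference cultivar could also be lost or moved between copies.

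The table lists 269207 gene identifiers, of which 107836 are high-confidence and 161371 low-confidence models by their suffix, and 159897 had 0 counts in every library. The table has 0 columns that belong to no sample. The deposited file does not pair the identifiers with names, and none of the 269207 matched the name table used here, which lists 155467 wheat genes under other identifiers. Chromosome and subgenome were read from the identifier. Functional lists that had been drawn up for iron uptake, photosynthesis and related processes rest on gene descriptions, and those for sequence motifs on transcripts. Neither could be applied, so the 5 lists tested were subgenomes A, B and D and the high- and low-confidence models.

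Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr on the groups). The 12 leaf libraries were fitted together for the 4 leaf comparisons, sharing 1 estimate of the spread (62841 genes, common biological coefficient of variation 0.34, normalization factors 0.82 to 1.28). The 6 libraries of day 11 were fitted for roots against leaves (67922 genes, 0.18, factors 0.95 to 1.05). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM are TMM-scaled within the libraries of the fit, unless stated to be scaled over all 15. Where all 3 libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group. The bound takes the mean of the other group and does not allow for its spread between plants. Where a group had 1 to 3 counts, the pooled ratio has an exact (Clopper-Pearson) 95% interval for counting error only.

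Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with adjusted p over the 5 lists of a comparison. The preset leaves little power for lists this large, so a list that camera did not call may still have moved. Principal components used log2 CPM with a prior count of 2. Genes were named by a rule: the 2 largest increases and the 2 largest decreases in log2 fold change per comparison among called genes with a mean of 5 CPM or more over both groups and the same direction in all 3 plants. The comparisons, their tests, the naming rule and the alternatives listed below were fixed before the data were examined. The removal of plant 1 on day 0 and plant 3 on day 7, the splits of the samples and, apart from that of neighbouring genes, the tests of further observations were chosen afterwards.

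On simulated counts with the real libraries' means and depths, edgeR recovered 50 of 100 genes changed 4-fold and 2 of 100 changed 2-fold for day 1 against day 0, with 1 false call among 62841 genes. For roots against leaves it recovered 69 of 100 changed 4-fold and 25 of 100 changed 2-fold, with 13 false calls among 67922 genes. The 13 false calls stand beside only the 69 and 25 recovered. Only these genes were changed in a simulation, whereas 46469 were called in the real comparison of roots and leaves. The adjusted p depends on the share of changed genes, so the recovery does not give the sensitivity of the real tests.

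Per the labels, 3 plants were used and each group carries their numbers, which were therefore taken to pair the libraries. The main fits had the group as their only term and did not use this pairing. The plant entered as a block among the alternatives and in the rule for naming genes. Deviations from the group means of leaf libraries from the same plant correlated across genes at -0.15 to 0.24 over 18 pairs (median 0, 4 pairs above 0.1), against -0.33 to 0.28 for 36 pairs of different plants (median 0, 2 pairs above 0.1), and at 0 to 0.02 for roots and leaves of day 11. The alternatives tried were RLE size factors, DESeq2 1.42.0, no low-count filter, a filter of at least 1 CPM in 3 libraries, high-confidence models only, the plant as a block, other sets of libraries in the fit, glmTreat against a log2 fold change of 1, and leaving out each plant.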

Results

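Gene expression was measured in leaves and roots of bread wheat (Triticum aestivum) cultivar Fielder, a spring wheat that is widely used for transformation, while the plants ran out of iron. Bread wheat is hexaploid, so most of its genes exist as copies on the A, B and D subgenomes. Seedlings in hydroponic boxes received a complete solution with 50 µM iron for 12 days and then a solution with 0 µM iron for 11 days. Messenger RNA was sequenced from 15 libraries in 5 groups of 3: the first leaf on day 0 of iron deficiency, the first leaf on day 1, the third leaf on day 7, the upper leaves from the third to the fifth on day 11, and the roots on day 11. The labels name 3 plants and repeat their numbers in each group, so libraries with the same number are called plant 1, 2 or 3 here, and the correlation of their deviations had a median of 0 over the same-number pairs of leaf libraries. Days 7 and 11 differ from day 0 in plant age and leaf position as well as in iron supply, and no iron-replete library of days 1, 7 or 11 entered the comparisons. Whether the groups shared a library or sequencing batch is not given in the sources used here. Only the contrast of day 1 with day 0 keeps the leaf position the same.

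The library totals ran from 15434838 counts in plant 3 on day 0 to 25552816 in the roots of plant 3. A group at 0 counts in all its libraries has a floor of 3 counts over the group, which was 0.0608 CPM (counts scaled to library size) for day 0 and 0.0439 CPM for day 7. These limits cover counting error only. Genes with at least 1 count numbered 65265 ± 3193 (SD, n = 3) in first leaves on day 0, 66929 ± 1251 on day 1, 71789 ± 1527 on day 7, 73602 ± 1485 in the day 11 leaves and 77290 ± 1723 in roots (SD, n = 3 each). Low-confidence gene models took 4.41% ± 0.08 of the counts on day 0, 4.08% ± 0.25 on day 1 and 4.54% ± 0.15 on day 7. Their share was 5.05% ± 0.05 in day 11 leaves and 5.52% ± 0.02 in roots (SD, n = 3 each). The subgenome shares differed little: D-subgenome genes took 34.01% ± 0.19 of the counts on day 0 and 34.7% ± 0.23 on day 7, and B-subgenome genes took 32.0% ± 0.04 and 31.5% ± 0.27 (SD, n = 3). An exact permutation test of 3 libraries against 3 cannot go below a two-sided p of 0.1, so these shares are given as levels.

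Tissue was the main axis among the 15 libraries, with roots apart from all leaves on the first principal component (60.9% of the variance) and the leaf stages spread along the second (19.2%). Among the 12 leaf libraries the first component (54.1%) ran from the first leaves of days 0 and 1 to the day 7 and day 11 leaves. The library of plant 1 on day 0 and that of plant 3 on day 7 lay between the other libraries of those days. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.906 to 0.922 between plants on day 0, 0.958 to 0.959 on day 1, 0.903 to 0.954 on day 7, 0.962 to 0.969 in day 11 leaves and 0.972 to 0.978 in roots. No pair of libraries in a group agreed within sampling noise, so each counts as 1 replicate.

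**Figure D1:**
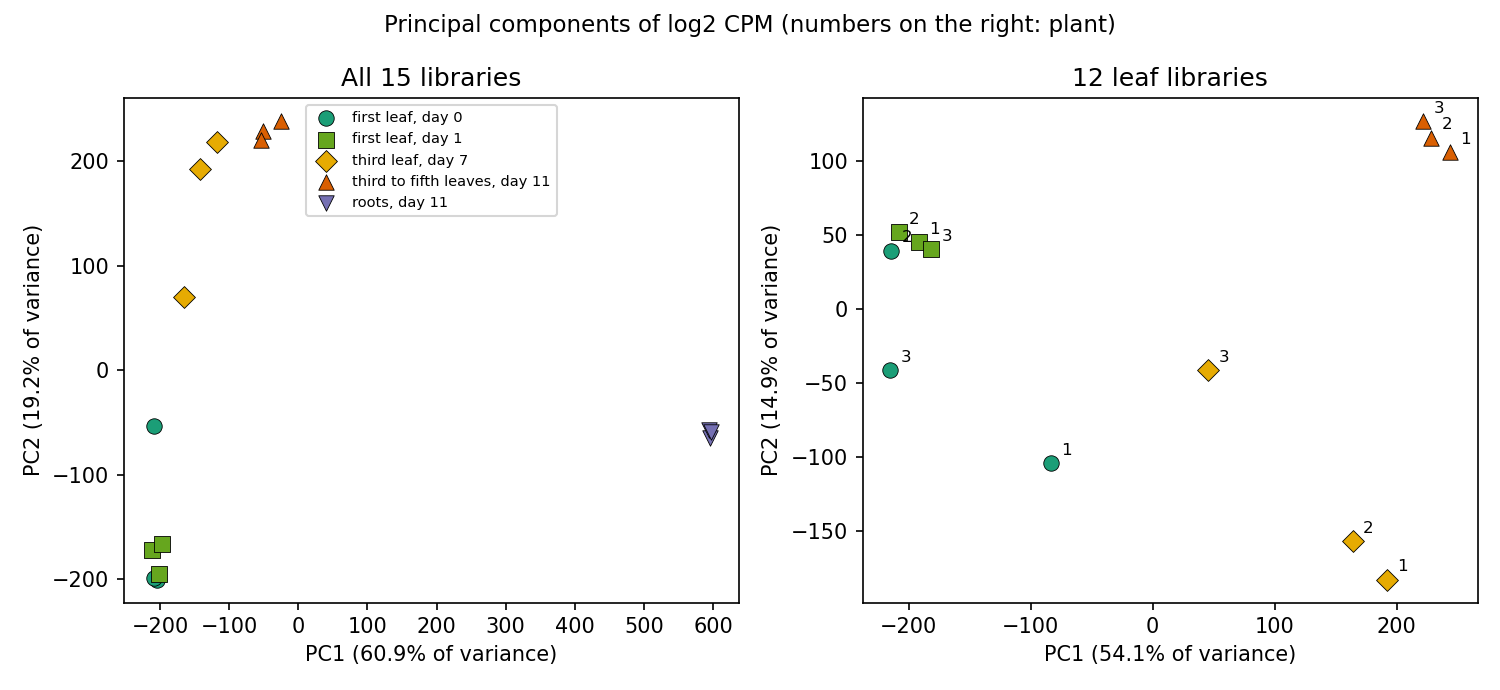
Scores of the libraries on the first and second principal components of log2 CPM, for all 15 libraries on the left and the 12 leaf libraries on the right, where the digits give the plant. The axes carry their percentage of the variance (60.9% and 19.2% on the left, 54.1% and 14.9% on the right), and on the right plant 1 of day 0 and plant 3 of day 7 sit between the rest of their groups.

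The gene identifiers carry the chromosome and subgenome but no function, and none matched the name table used here, so genes are given by identifier. For each comparison the text names the pair with the largest increases and the pair with the largest decreases among genes called by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), at a mean of 5 CPM or more and with the same direction in all 3 plants.

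The first comparison sets the first leaf after 1 day without iron against the first leaf before withdrawal, and time and iron supply differ together in it. Of 62841 genes tested, 477 were higher and 336 lower on day 1 than on day 0, which is 1.3% of the genes. TraesCS3A02G004400LC, a low-confidence model on chromosome 3A, went from 0 counts in all 3 day 0 libraries to 10.7 CPM ± 2.2 (SD, n = 3), at least 175-fold higher (edgeR adjusted p = 0.049). TraesCS2B02G495300LC on chromosome 2B rose from 0.0369 CPM ± 0.032 to 11.8 CPM ± 6.51 (SD, n = 3; edgeR log2 fold change 7.99, SE 1.67, adjusted p = 0.048). With 2 counts in the day 0 group, its pooled ratio was 287, with a 95% counting interval of 79.2 to 2380. TraesCS2D02G006500 on chromosome 2D fell from 12.0 CPM ± 17.3 to 0.0633 CPM ± 0.11 (SD, n = 3; edgeR log2 fold change -7.31, SE 1.44, adjusted p = 0.04), and 602 of its 666 day 0 counts came from plant 1. TraesCS5B02G232700 on chromosome 5B fell from 9.94 CPM ± 5.89 to 0.0909 CPM ± 0.157 (SD, n = 3; edgeR log2 fold change -6.70, SE 0.83, adjusted p = 0.0074).

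In later samples these genes stood at different levels. TraesCS5B02G232700 stood at 9.9 CPM ± 1.49 in the third leaf on day 7 and at 8.32 CPM ± 3.35 on day 11 (SD, n = 3, scaled over all 15 libraries), beside 10.6 CPM ± 6.21 on day 0. TraesCS2D02G006500 stood at 112 CPM ± 38.4 on day 7 and 74.8 CPM ± 15.7 on day 11. TraesCS3A02G004400LC was at 0 in 2 of the 3 day 7 libraries and at 0.0137 CPM ± 0.0237 in day 11 leaves, while roots held 5.51 CPM ± 1.06.

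The day 1 calls were spread over the subgenomes. On subgenomes A, B and D, 151, 156 and 162 genes were higher, and 0.6%, 0.5% and 0.6% of those tested were lower. Adjusted over the list alone, the higher genes numbered 160, 149 and 177 and the lower genes 124, 97 and 132. High-confidence models gave 423 higher and 309 lower genes of 51457 (adjusted over the list alone, 481 and 363). Low-confidence models gave 54 and 27 of 11384 (adjusted over the list alone, 30 and 12). None of the 5 lists was called against the other genes (camera in limma, adjusted p = 1 for each). With the preset correlation of 0.01 camera has little power for lists this large, so differences between the lists stay open. The correlations estimated for subgenomes A, B and D were 0.00088, 0.00058 and 0.00075, and with estimated correlations no list was called either. Camera's direction is relative to the other genes, so it can differ from the sign of a list's own median and mean. Subgenome B had a direction of up with a median log2 fold change of -0.01 and a mean of -0.10. With the plant as a block 324 genes were called, of which 292 were among the 813, and DESeq2 called 4613, of which 45.2% were higher against 58.7% by edgeR. The call of 3 of the 4 named genes ended under the block (adjusted p = 0.077 for TraesCS3A02G004400LC, 0.053 for TraesCS2B02G495300LC and 0.086 for TraesCS2D02G006500). Without plant 1 or plant 2 all 4 calls ended, and without plant 3 those of TraesCS5B02G232700 (edgeR adjusted p = 0.063) and TraesCS2D02G006500 (0.13). Without the day 0 library of plant 1, those of TraesCS3A02G004400LC (0.076) and TraesCS2B02G495300LC (0.097) ended. Over the alternatives the adjusted p ran from 0.003 to 0.26 for TraesCS3A02G004400LC, 4.9e-05 to 0.34 for TraesCS2B02G495300LC, 6.1e-06 to 0.22 for TraesCS2D02G006500 and 7.5e-13 to 0.15 for TraesCS5B02G232700. The call of TraesCS2D02G006500 also ended with only the 6 libraries of days 0 and 1 in the fit (0.091). Its log2 fold change was -4.75 without the day 0 library of plant 1, -4.27 without plant 1 and -11.54 without plant 3. That of TraesCS5B02G232700 was -5.54 without plant 3 and -11.06 without plant 2. The values of -11.54 and -11.06 leave day 1 at 0 counts and depend on the prior count. edgeR called 0 genes without plant 1 (7828 at an unadjusted p under 0.05), 0 without plant 2 (8002 unadjusted) and 88 higher and 27 lower genes without plant 3. It called 1543 without the day 7 library of plant 3, which belongs to neither group compared.

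**Figure D2:**
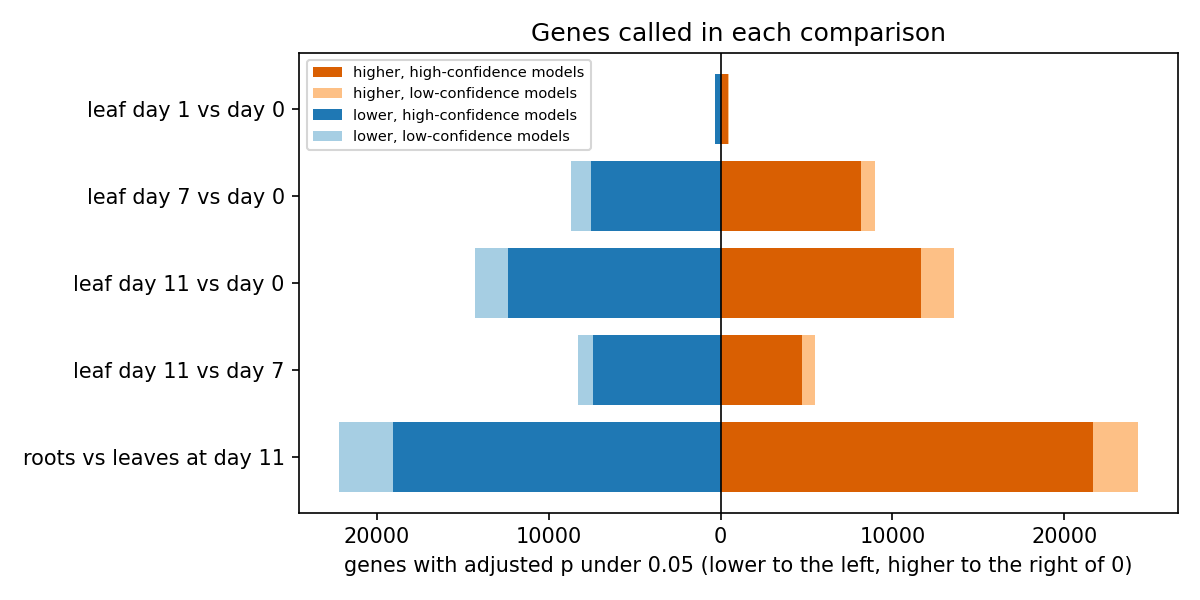
Number of genes with an edgeR adjusted p under 0.05 in each of the 5 comparisons, with genes lower in the first-named group to the left of 0, genes higher to the right, and low-confidence models in the paler shade. The bars run from 336 lower and 477 higher genes for day 1 against day 0 to 22194 lower and 24275 higher genes for roots against leaves at day 11.

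The second comparison sets the third leaf after 7 days without iron against the first leaf before withdrawal. Here 9006 genes were higher and 8726 lower (28.2% of those tested), of which 5955 and 5359 differed by at least 2-fold. TraesCS3D02G260500 on chromosome 3D rose from 0 counts in all day 0 libraries to 216 CPM ± 277 (SD, n = 3), at least 3550-fold higher (edgeR adjusted p = 0.0059), with 568, 114 and 11.3 CPM in plants 1, 2 and 3 when scaled over all 15 libraries. TraesCS5D02G446800 on chromosome 5D rose from 0 to 142 CPM ± 161 (SD, n = 3), at least 2330-fold higher (edgeR adjusted p = 0.0078). Its values of 341, 110 and 4.23 CPM ran in the same order of plants. Both bounds hold for the mean of day 7 only, and plant 3 on its own fell short of them. TraesCS4D02G358100 on chromosome 4D fell from 99.6 CPM ± 112 to 0.0153 CPM ± 0.0265 (SD, n = 3; edgeR log2 fold change -12.24, SE 1.88, adjusted p = 0.0013). A single count remained on day 7, and the pooled ratio of day 0 to day 7 was 5940 with a 95% counting interval of 1070 to 235000. Its day 0 counts were 851, 440 and 2995 in plants 1, 2 and 3, and its log2 fold change was -10.36 without plant 3 and -14.48 without plant 2, which leaves day 7 at 0 counts. TraesCS1A02G334700 on chromosome 1A fell from 14.6 CPM ± 3.89 to 0 in all day 7 libraries (SD, n = 3), at least 333-fold lower (edgeR adjusted p = 0.00014), and was also at 0 in every day 11 leaf and root library.

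More of the called genes rose from 0 counts than fell to 0. Between day 0 and day 7, 886 of the called genes rose from 0 counts in every day 0 library and 209 fell to 0 in every day 7 library. The floor was 0.0608 CPM on day 0 and 0.0439 CPM on day 7, so a gene at a low level reads 0 more easily on day 0. How much of the excess this makes was not tested. Subgenomes A, B and D held 2923, 2899 and 3069 higher genes and 2891, 2927 and 2795 lower genes. Adjusted over the list alone these were 2930, 2862 and 3104 higher and 2892, 2903 and 2818 lower. Of the high-confidence models 8176 were higher and 7518 lower (adjusted over the list alone, 8516 and 7745). Of the low-confidence models 830 were higher and 1208 lower (adjusted over the list alone, 618 and 992). No list was called against the other genes (camera adjusted p = 0.93 for each). Subgenomes A and B and the low-confidence models had a camera direction of down with positive median and mean log2 fold changes. The call of TraesCS3D02G260500 ended without plant 2 (edgeR adjusted p = 0.1), and that of TraesCS5D02G446800 without plant 1 (0.051) or plant 2 (0.11). Over the alternatives their adjusted p ran from 3.1e-09 to 0.1 and from 4.5e-10 to 0.11. The number of called genes was 9419 without plant 1, 2389 without plant 2 and 8034 with only the 6 libraries of days 0 and 7 in the fit.

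The third comparison sets the upper leaves after 11 days without iron against the first leaf before withdrawal. In these leaves 13560 genes were higher and 14295 lower (44.3% of those tested). Of these, 9068 and 10257 differed by at least 2-fold, and 2323 and 1675 by at least 16-fold, so the direction in excess depended on the cut. TraesCS3A02G489700 on chromosome 3A rose from 0 counts on day 0 to 443 CPM ± 74 (SD, n = 3), at least 7280-fold higher (edgeR adjusted p = 3.1e-06). It was already at 26.1 CPM ± 9.56 in day 7 leaves and stood at 158 CPM ± 23.1 in roots (SD, n = 3, scaled over all 15 libraries). TraesCS6B02G425200 on chromosome 6B rose from 0 to 378 CPM ± 178 (SD, n = 3), at least 6220-fold higher (edgeR adjusted p = 2e-04), having been at 0 in every leaf library of days 0, 1 and 7.

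Other genes fell to 0 or near 0 by day 11. TraesCS3D02G162500 on chromosome 3D fell from 124 CPM ± 26.6 to 0.0126 CPM ± 0.0219 (SD, n = 3; edgeR log2 fold change -12.68, SE 1.44, adjusted p = 4.9e-05), with a pooled ratio of 9530 and a 95% counting interval of 1710 to 376000 that rests on 1 count, in plant 2. Without plant 2, which leaves day 11 at 0 counts, its log2 fold change was -14.17. TraesCS1B02G451900 on chromosome 1B fell from 29.1 CPM ± 7.55 to 0 in all day 11 leaves (SD, n = 3), at least 749-fold lower (edgeR adjusted p = 3.4e-06), with 12.9 CPM ± 5.99 on day 1 and 5.16 CPM ± 0.562 on day 7 in between. From day 0 to day 11, 1381 called genes rose from 0 counts and 618 fell to 0. The floor of 0.0388 CPM on day 11, against 0.0608 CPM on day 0, again favours rises from 0.

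**Figure D3:**
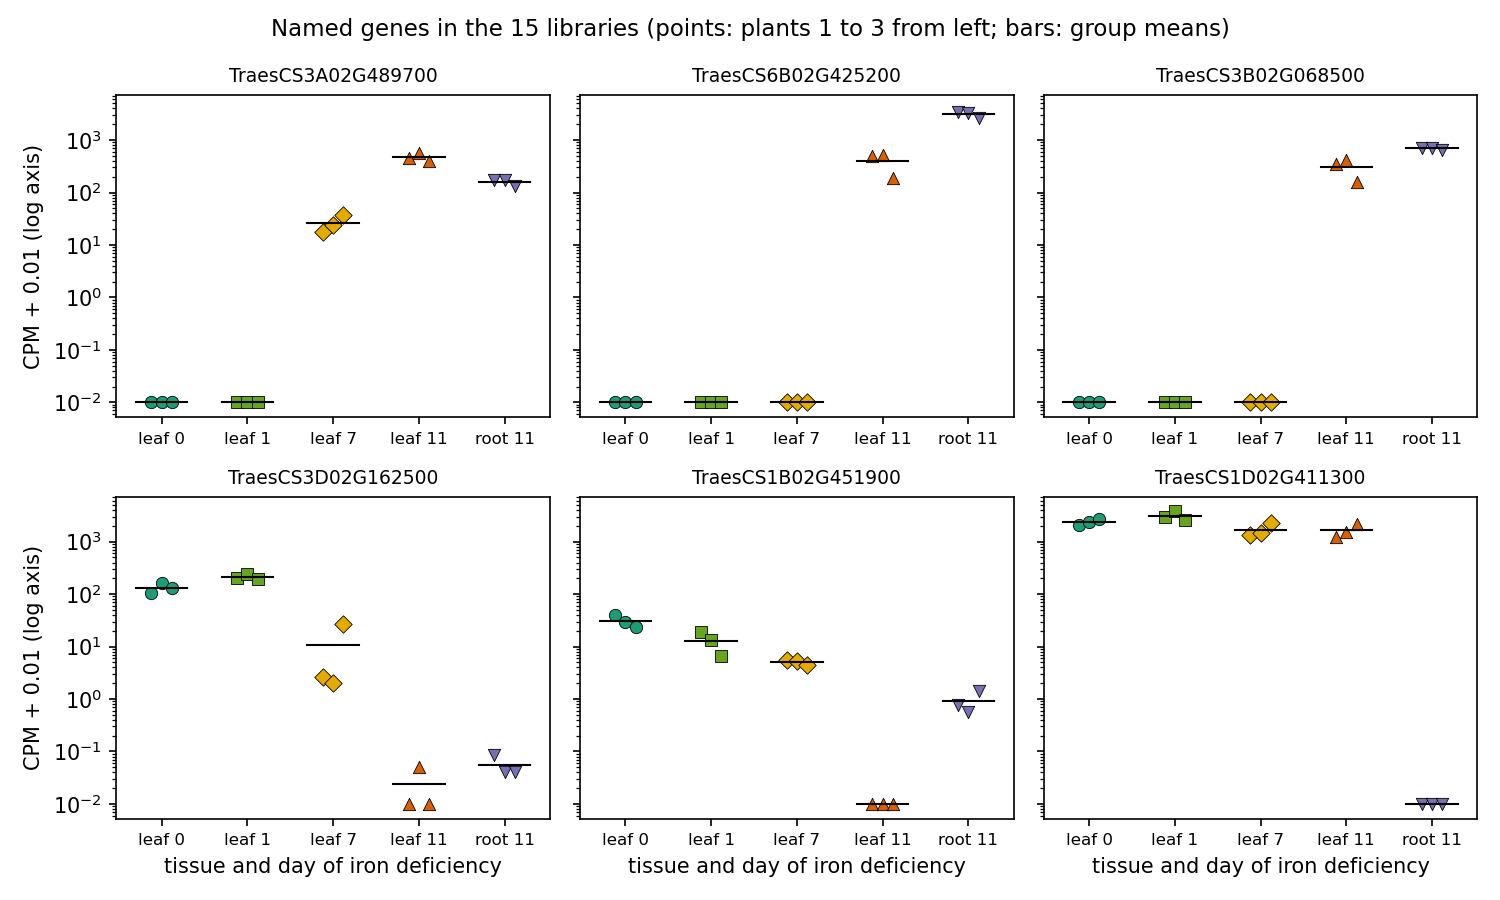
CPM plus 0.01 on a log axis, scaled over all 15 libraries, of 6 named genes in the 5 groups, with 1 point per plant and a bar at the group mean; points at 0.01 are libraries with 0 counts. TraesCS3A02G489700 is at 26.1 CPM on day 7 and 473 CPM in day 11 leaves, TraesCS6B02G425200 and TraesCS3B02G068500 are at 0 in the 9 leaf libraries up to day 7, and TraesCS1D02G411300 is at 0 in the roots.

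The day 11 changes again ran through all subgenomes. Subgenomes A, B and D held 4462, 4363 and 4584 higher genes and 4732, 4809 and 4563 lower genes, of 20526, 21080 and 20412 tested. Adjusted over the list alone these were 4477, 4336 and 4595 higher and 4743, 4796 and 4578 lower. High-confidence models gave 11696 higher and 12347 lower genes (adjusted over the list alone, 11842 and 12463). Low-confidence models gave 1864 and 1948 (adjusted over the list alone, 1648 and 1804). None of these lists was called (camera adjusted p = 0.92 for each). Subgenomes A and B and the high-confidence models had a camera direction of down with positive median and mean log2 fold changes. Each named gene of this comparison kept an adjusted p under 0.05 in all of its 15 alternative analyses. Without plant 2 the called genes numbered 16494.

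The fourth comparison sets the upper leaves of day 11, from the third to the fifth, against the third leaf of day 7. Leaf positions overlap but are not the same, and plant age, leaf position and time without iron differ together. Decreases were the more frequent among all called genes: 8277 genes were lower and 5490 higher (21.9% of those tested), and 5130 and 2879 of them differed by at least 2-fold. Among the largest changes increases were the more frequent. By at least 16-fold, 523 were lower and 672 higher, and 306 fell to 0 counts while 403 rose from 0. The floors of 0.0388 CPM on day 11 and 0.0439 CPM on day 7 favour rises from 0. TraesCS6B02G425200 rose from 0 counts on day 7, at least 8620-fold (edgeR adjusted p = 0.00065). TraesCS3B02G068500 on chromosome 3B rose from 0 to 286 CPM ± 126 (SD, n = 3), at least 6530-fold higher (edgeR adjusted p = 0.00053). TraesCS3A02G280700 on chromosome 3A fell from 151 CPM ± 146 to 1.63 CPM ± 0.788 (SD, n = 3; edgeR log2 fold change -6.53, SE 1.02, adjusted p = 0.0013). TraesCSU02G050500, which has no assigned chromosome, fell from 28.6 CPM ± 30.9 to 0.335 CPM ± 0.176 (SD, n = 3; edgeR log2 fold change -6.38, SE 1.16, adjusted p = 0.0031). Both were at 0 in all roots. Their day 7 values ran from 16 to 326 CPM and from 1.97 to 67 CPM across plants when scaled over all 15 libraries.

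Between day 7 and day 11 the high-confidence models held 7452 lower and 4748 higher genes (adjusted over the list alone, 7657 and 4908). The low-confidence models held 825 lower and 742 higher (adjusted over the list alone, 643 and 531). The high-confidence list had a camera adjusted p of 0.053 towards lower values, with an adjusted p = 0.0027 with an estimated correlation and 0.048 with the plant as a block. The low-confidence list had 0.053 towards higher values, with an adjusted p = 0.25 with an estimated correlation and 0.048 with the block. Together both lists hold all genes tested, so camera with the preset correlation gave them the same p in opposite directions, which is 1 result. Subgenomes A, B and D held 1793, 1794 and 1846 higher genes and 2735, 2750 and 2694 lower genes. Adjusted over the list alone these were 1798, 1784 and 1856 higher and 2736, 2737 and 2710 lower. No subgenome was called (camera adjusted p = 0.94 for each). The camera direction of B and D was up beside negative medians and means. The excess of lower genes was absent when only the 6 libraries of days 7 and 11 were fitted, where 7661 genes were higher and 6980 lower, and larger without plant 2, where 29.3% of the called genes were higher against 39.9%. The number of called genes was 5149 without plant 1 and 3357 without plant 2. The calls of TraesCS3A02G280700 (edgeR adjusted p = 0.059) and TraesCSU02G050500 (0.078) ended without plant 2. Over the alternatives their adjusted p ran from 6.4e-12 to 0.059 and from 1.8e-11 to 0.078. Without plant 3 their log2 fold changes were -5.56 and -4.95, and without the day 7 library of plant 3 alone -5.48 and -5.06.

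The fifth comparison sets roots against leaves of the iron-deficient plants on day 11. Of 67922 genes tested, 24275 were higher and 22194 lower in roots (68.4%), with 8233 and 6785 differing by at least 16-fold. TraesCS1B02G239200 on chromosome 1B stood at 513 CPM ± 64.2 in roots and at 0 in all day 11 leaves (SD, n = 3), at least 10100-fold higher (edgeR adjusted p = 1.3e-06). TraesCS5A02G529900 on chromosome 5A stood at 248 CPM ± 10.4 in roots and 0 in leaves (SD, n = 3), at least 4890-fold higher (edgeR adjusted p = 6.7e-07). TraesCS1D02G411300 on chromosome 1D stood at 2014 CPM ± 596 in leaves and 0 in roots (SD, n = 3), at least 48200-fold lower in roots (edgeR adjusted p = 5e-06). TraesCS6D02G340700 on chromosome 6D stood at 1287 CPM ± 219 in leaves and 0 in roots (SD, n = 3), at least 30800-fold lower in roots (edgeR adjusted p = 2e-06).

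The leaf genes were also present, and the root genes absent, in the earlier leaves. TraesCS1B02G239200 and TraesCS5A02G529900 had 0 counts in all 12 leaf libraries, while TraesCS1D02G411300 was at 2380 CPM ± 306 and TraesCS6D02G340700 at 3030 CPM ± 349 in first leaves on day 0 (SD, n = 3, scaled over all 15 libraries). Among the called genes, 4878 had counts in roots and 0 in all day 11 leaves, and 3434 had counts in leaves and 0 in all roots. The floors in this fit, 0.0418 CPM for roots and 0.0508 CPM for leaves, favour the first of these numbers. Subgenomes A, B and D held 7913, 8050 and 7949 genes higher in roots and 7216, 7371 and 7310 lower. Adjusted over the list alone these were 7915, 8037 and 7956 higher and 7217, 7359 and 7316 lower. No subgenome was called (camera adjusted p = 0.98 for each). High-confidence models gave 21699 higher and 19040 lower genes (adjusted over the list alone, 21821 and 19126). Low-confidence models gave 2576 and 3154 (adjusted over the list alone, 2377 and 2914). Both lists had a camera adjusted p of 0.58. Subgenomes A and D had a camera direction of down with positive medians and means. No root library from before iron withdrawal was analysed here, so this contrast is one of tissue within deficient plants.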

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

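The removals of plant 1 on day 0, of plant 3 on day 7 and of both were chosen after seeing the data. The tests of other splits of the samples were likewise chosen after the result was seen; the other alternatives were planned. Against the 813 genes of day 1 and day 0, DESeq2 called 4613, the fit with the plant as a replicate block 324, the fit of all 15 libraries 1561 and glmTreat 41. Leaving out libraries gave 0 to 1543, and 1490 without both libraries named above. For day 7 and day 0 (17732 genes), the fit of only the 6 libraries of both groups called 8034 and glmTreat 2823, and leaving out libraries gave 2389 to 22823. For day 11 and day 0 (27855) glmTreat called 10411 and leaving out libraries 16494 to 30215. The same counts for day 11 and day 7 (13767) were 2255 and 3357 to 16436, and for roots and leaves (46469), 27293 and 39894 to 44507. The glmTreat counts are lower because it tests against a 2-fold change; the cause was not tested for the other alternatives. RLE factors, no low-count filter, the filter at 1 CPM and high-confidence models only each moved a count by less than 1.5 times. The share of higher genes moved by over 10 percentage points for day 1 and day 0 (58.7%) by DESeq2 (45.2%), with 6 libraries (70.4%) and without plant 3 (76.5%), and for day 11 and day 7 (39.9%) with 6 libraries (52.3%) and, the other way, without plant 2 (29.3%). Smaller moves turned the direction in excess under some alternatives in the other comparisons. The share went from 48.7% to 55.8% for day 11 and day 0 without both libraries named above. For day 7 and day 0 it went from 50.8% to 42.7% with 6 libraries, and for roots and leaves from 52.2% to 47.6% with all 15 libraries. Camera called 0 of 25 list tests (2 at an unadjusted p under 0.05), 1 with an estimated correlation, 9 by fry, which does not compare a list with other genes, and 2 with the replicate block. Without plant 1 on day 0 and plant 3 on day 7, camera called the high-confidence list lower and the low-confidence list higher for day 11 against day 7 (adjusted p = 0.022 each, and 0.0055 and 0.062 with an estimated correlation). Together both lists hold all genes tested, so with the preset correlation their calls are 1 result seen from either side. The same holds for the 2 tests at an unadjusted p under 0.05 and the 2 calls with the replicate block. No call of a comparison other than those given turned with the block, which called 16220, 26503, 11928 and 43630 genes in the later comparisons.

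Under the alternatives, 258 values of named genes kept the direction and the call, 24 kept the direction but lost the call, and none reversed. Of the 24, 15 came from leaving out a plant, 3 from the block and 3 from glmTreat. In simulated data 2 of 100 genes changed 2-fold were called for day 1 against day 0 and 25 of 100 for roots against leaves. The common biological coefficient of variation was 0.34 and 0.18 in these fits, and depth was not varied. Fewer genes were changed there than edgeR called in the real comparisons, so these shares do not give the recovery of the real tests. Depth limits the levels that can be seen: a gene at 0 in all day 0 libraries can hold up to 0.0608 CPM.

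With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes as the real one. The highest count of another split was 18 against 813 for day 1 and day 0, 10 against 17732 for day 7 and day 0, 0 against 27855 for day 11 and day 0, 1 against 13767 for day 11 and day 7, and 0 against 46469 for roots and leaves. Among the other splits that part the pairs of all 3 plants, as the real one does, the highest counts were 10, 10, 0, 1 and 0. The rest keep the pair of some plant together. Every other split puts libraries of both real groups on each side. A real difference then adds to the spread within the sides and lowers the count. The low counts of other splits therefore do not measure what random labels would give, and nothing is concluded from them.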

Other observations

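Apart from the test of neighbouring genes, the tests in this part were chosen after the patterns had been seen. The changes between early and late leaves were shared by comparisons that have no library in common. Of the 9006 genes higher on day 7 than on day 0, 6293 (69.9%) were also higher on day 11 than on day 1, against 2192 for independent lists, and of the 8726 lower genes 7069 (81.0%) were also lower, against 2035. Opposite directions were called for 286 genes. Across 62841 genes, which are not independent replicates, the log2 fold changes had a Pearson's r of 0.63 and a Spearman's rho of 0.68. Both comparisons came from the same fit, with a shared estimate of the spread, and from the same plant numbers. Genes with high counts or little spread can be called more easily in both, so the numbers for independent lists are no exact expectation. Age, leaf position and iron supply all differ between the early and late leaves in both comparisons.

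Among genes higher in roots than in the first leaves of day 1, more were higher than lower in the leaves of days 7 and 11. The list holds 3220 genes with at least 5 CPM in roots and at least 4-fold more than in day 1 leaves; neither group enters the contrasts that follow. On day 7 against day 0, 902 were higher and 173 lower by edgeR's call, with a median log2 fold change of 0.68. On day 11 against day 0, 1561 (48.5%) were higher and 213 (6.6%) lower, with a median of 1.37, against at most 0.21 in 10000 random lists matched on leaf expression. With genes at 0 in either group set to their bound or to no change, the medians were 0.65 and 1.35. The median log2 CPM of the list was 0.51 to 0.8 in the 3 day 0 libraries, 1.06 to 1.68 on day 7 and 1.84 to 2.16 on day 11. The roots that define the list were harvested on day 11 without iron. The list therefore also selects genes raised by age, harvest day or iron loss in any tissue. It further selects genes low in day 1 leaves relative to roots, and these leaves share the leaf position of day 0. The random lists were matched on leaf expression without this condition. Genes low in first leaves at a matched leaf expression tend to be higher in later leaves, so a positive median was favoured beforehand. The medians of 0.68 and 1.37, and their distance from the random lists, cannot be told apart from these selections.

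Some root-abundant genes were detected in leaves on day 11 and in no earlier leaf library. Of 68 genes with at least 100 CPM in roots and 0 counts in the 9 leaf libraries of days 0, 1 and 7, 35 had counts in all 3 day 11 leaf libraries, 24 stood at 50 CPM or more there and 13 were at 0 in all 3. TraesCS6B02G425200 is the example with the highest root level, at 405 CPM ± 190 in leaves and 3110 CPM ± 427 in roots (SD, n = 3, scaled over all 15 libraries), whereas TraesCS1B02G239200 is at 0 in leaves and 402 CPM in roots on the same scale. Root RNA carried into the leaf samples would give every gene about the same leaf-to-root ratio, but the ratio ran from 0% to 87.4% with a median of 0.602%. Of the genes, 27.9% lay below 0.1 times that median, and 25% and 42.6% lay below 0.1 times the library's own median in plants 1 and 2, which argues against it as the whole cause. The levels in plant 3 were too low for this test. Depth is argued against as well, since the 9 earlier libraries hold 3.03 times the counts of the 3 day 11 leaf libraries. Expression tied to iron deficiency and expression tied to leaf position or age cannot be told apart, because 0 iron-replete leaf libraries of day 7 or 11 are among the samples.

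The class differed between plants and sat partly in clusters. Its summed level was 4459, 5228 and 1442 CPM in the day 11 leaves of plants 1, 2 and 3, and its median level 3.39, 2.35 and 0.086 CPM. By identifier order, 11 of 63 placed high-confidence members had another member within 10 steps, against a median of 2 and at most 8 in 1000 random lists of root-expressed genes. Not all of these were clearly present in day 11 leaves. TraesCS1B02G239200 and TraesCS1B02G239900 were at 0 there, and the pairs on chromosomes 1D and 7D at 0.043 to 0.192 CPM. Those on 6A and 6D stood at 18.2 to 108 CPM. The clusters thus describe the class and not its detection in day 11 leaves. The members fell on subgenomes A (23), B (19) and D (25), with 1 unplaced.

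The libraries of plant 1 on day 0 and plant 3 on day 7 lie between the groups of those days. An exchange of labels between them is argued against, because each correlates better with its own group than with the other, by 0.032 at the least in Pearson's r. Day 0 RNA that diluted plant 3 of day 7 would need a share of 0.86 from 580 genes high on day 7, but 23 genes low on day 7 put it at 0.07 (10th to 90th percentile 0.01 to 0.29), a difference of 0.79; a small share stays open. Day 7 RNA in plant 1 of day 0 stays open too: of 97 genes absent from the other early libraries and above 10 CPM in plants 1 and 2 on day 7, 18.6% lay at 0 or below 0.1 times the median share, but the day 7 libraries themselves differ by a median of 13.2-fold in these genes, so no common share was to be expected. The within-group contrasts of both libraries correlated at r = 0.3 across genes (second of the 9 choices of a library per day 0.19), but the libraries were picked for lying towards each other, so this value decides nothing about a shared axis of variation. Differences in leaf stage or response between plants stay open and were not tested.

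Genes called in the same direction lay next to each other more often than in shuffles. For day 11 against day 0, 6566 pairs of neighbouring high-confidence genes shared a direction, against a median of 5569 and at most 5753 in 1000 shuffles within chromosomes, and for roots against leaves there were 16299 pairs, against at most 14889. Neighbours were genes next to each other in identifier order among those tested, with untested genes skipped. The shuffles moved called and uncalled genes alike, so the excess can also come from called genes lying together, whatever their direction. Reads shared between neighbouring duplicates were not examined.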
